A study of Mus musculus with 14 samples.

How the data were processed

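RNA sequencing was done on the intima of the thoracic aorta of mice lacking apolipoprotein E. Per the labels' protocols, the aorta was perfused with saline, freed of fat and of its arch, and QIAzol was run through the lumen so that the inner layer of the vessel was lysed. Lysates of 12 to 14 mice of 1 genotype were pooled into each of the 14 libraries. The pools are therefore separate sets of animals, and p-values measure the spread between pools, not between single mice. Polyadenylated RNA was selected from 100 ng of total RNA and made into strand-specific libraries with a directional NEBNext kit.

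The authors deposited estimated counts per gene from RSEM, which need not be whole numbers because a read that fits several transcripts is divided among them. Per the submitters' processing notes, the tools were Trim Galore 0.6.10, cutadapt 4.1, STAR 2.7.10b, RSEM 1.2.28 and limma (no version), on the genome build GRCm38. The annotation release, the strand setting and the filters are not given in the sources used here. The authors also deposited log2 values normalised with limma voom for 13034 genes. Those genes were the 13034 genes of the count table with over 1 CPM, the count scaled to a library total of 1000000, in at least 3 libraries. In each library the deposited log2 values equalled log2 CPM computed with 0.5 added to each count and 1 to the library total, shifted by 1 constant per library of between -0.05 and 0.07, with a largest departure of 1.8e-15. The deposited log2 values served only as an alternative.

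The count table held 22430 genes with Ensembl identifiers and symbols. Positions came from the GENCODE M21 annotation of GRCm38, which matched 22311 identifiers, 21780 of them annotated as protein coding, and did not match 119. Starts and ends are those of the whole annotated gene, exons, introns and untranslated regions included. Library totals ran from 27169800 to 35692400 estimated counts. Genes with near-identical copies, among them the cytosolic ribosomal protein genes with their processed pseudogenes, are uncertain because RSEM divides shared reads by a model.

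Libraries were grouped by the genotype in their labels: wild-type control (4), ubiquitous progerin (3), lamin C-only control (4) and VSMC progerin (3), where VSMC stands for vascular smooth muscle cell. Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr by group (minimum count 10, minimum total 15, share of the smallest group 0.7), which left 14269. Counts were scaled by the trimmed mean of M-values (TMM) and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust dispersion, in 1 fit of all 14 libraries with a mean per group. Each comparison was adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05 with no fold minimum. The comparisons were the 3 that the study names, plus the difference between the ubiquitous progerin and VSMC progerin effects. Both progerin effects have their own control libraries and share none. Standard errors (SE) of log2 fold changes were the absolute log2 fold change divided by the square root of F. Levels are TMM-scaled CPM, and log2 CPM used a prior count of 2. Intervals and p-values do not cover errors made in dividing reads among genes.

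Gene lists, 29 in all with 5 to 28 members, were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 29 lists within a comparison. Camera asks whether the genes of a list rank higher or lower than the other genes. It was run again with the correlation estimated from the data. The fry test was also run, whose p asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Members called over all genes tested, and members called when adjusted over the list alone, were counted. The groups, the comparisons, the tests, the gene lists, the rule for named genes and the first list of alternative settings were fixed before the data were examined.

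Named genes followed a rule. It took Lmna and Apoe in every comparison. It took the 5 higher and 5 lower genes with the largest absolute log2 fold change among those called with a mean log2 CPM of at least 2, log2 CPM ranges that do not overlap between both groups, and a symbol that is not a predicted gene. It took up to 4 called members with the smallest p from each of the 5 lead lists (endothelial identity, mesenchymal transition, smooth muscle contractile, TGF-beta signalling, and fibrillar and basement membrane collagen) and up to 2 from every other list. For the difference of effects it took 4 genes per direction. Fewer are named, some of the genes it took are not reported here, and genes outside the rule are said to be chosen after their values were seen. Xist, Mx1 and Mx2 were not analysed here.

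The steps were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by a known fold. All groups shared 1 mean per gene apart from these changes. In the real progerin comparisons 54.6% and 42.0% of genes were called, so the rates below may not hold there. For ubiquitous progerin against wild-type control, over 14037 genes, 62.0%, 82.0% and 86.7% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, and 6.79% of calls were false. For VSMC progerin against lamin C-only control, over 14049 genes, these shares were 57.5%, 55.0% and 95.0%, with 5.56% of calls false. For the comparison of both controls, over 14027 genes, they were 62.2%, 80.7% and 86.9%, with 4.46% false. For the difference of effects, over 14054 genes, they were 45.0%, 65.1% and 77.2%, with 3.20% false. Replicates of a group differed by far more than counting noise, with a chi-square per degree of freedom of 9.54 to 37.9 for each pair over genes with at least 20 counts, so no library was counted as a copy of another.

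Alternatives were edgeR's RLE size factors, no filter beyond 1 count in all libraries, a filter of 1 CPM in 3 libraries, limma-voom, the DESeq2 1.42.0 Wald test, only the groups compared, a minimum absolute log2 fold change of 1, unrounded counts, the deposited log2 values, the pool number as a block, each library left out in turn, an adjusted p under 0.1 for the overlap, and for lists the estimated correlation and fry. Leaving out the mitochondrially encoded genes, and the genes within 20 Mb of Lmna, was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 from tables handled with pandas 2.3.3 and numpy 2.4.6.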

Results

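Gene expression was measured in the aortic intima, the endothelium-lined inner layer of the vessel wall, of atherosclerosis-prone mice without apolipoprotein E. The 14 libraries fell into 4 groups. In the ubiquitous progerin group (3 libraries) both Lmna copies carried the G609G change, by which cells make progerin, the truncated lamin A of Hutchinson-Gilford progeria. These mice were set against mice with wild-type Lmna (4 libraries). In the VSMC progerin group (3 libraries) a Cre recombinase under the SM22α promoter turned on progerin in vascular smooth muscle cells of mice that otherwise make lamin C only. These were set against lamin C-only mice without Cre (4 libraries). Estimated counts per library totalled 28242600 to 31978600 in wild-type control, 27169800 to 29309800 in ubiquitous progerin, 31701300 to 35692400 in lamin C-only control and 27730500 to 33029100 in VSMC progerin. Of 22430 genes, 14269 had enough counts to be tested, with a common dispersion of 0.0187.

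Lmna, which encodes lamins A and C and progerin (ENSMUSG00000028063, GRCm38 chromosome 3, 88480147 to 88509956), was present in every library. Its level lay between 113 and 125 CPM in the wild-type control libraries, 115 and 121 CPM in ubiquitous progerin, 126 and 142 CPM in lamin C-only control and 207 and 256 CPM in VSMC progerin. Counts per gene do not separate lamin A, lamin C and progerin, so these levels do not check the alleles. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), the gene disrupted in all mice, gave 56.0 to 62.0, 50.7 to 54.1, 58.8 to 72.1 and 44.5 to 59.7 CPM in the same order, and counts per gene do not show which part of the disrupted gene was transcribed.

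The first 3 principal components held 38.2%, 26.5% and 6.20% of the variance. The controls lay together on the negative side of the first component, and the progerin groups lay on its positive side and on opposite sides of the second. Wild-type control pool 1 stood apart on the third, at 65.0 against -14.4 to 7.75 for the other libraries, and had counts for 14328 genes where the other wild-type pools had 15188 to 15233. Mitochondrially encoded genes took 5.01% ± 0.36 (SD, n = 4) of the counts in wild-type control, 7.68% ± 0.48 (n = 3) in ubiquitous progerin, 4.02% ± 0.45 (n = 4) in lamin C-only control and 11.8% ± 0.28 (n = 3) in VSMC progerin.

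**Figure D1:**
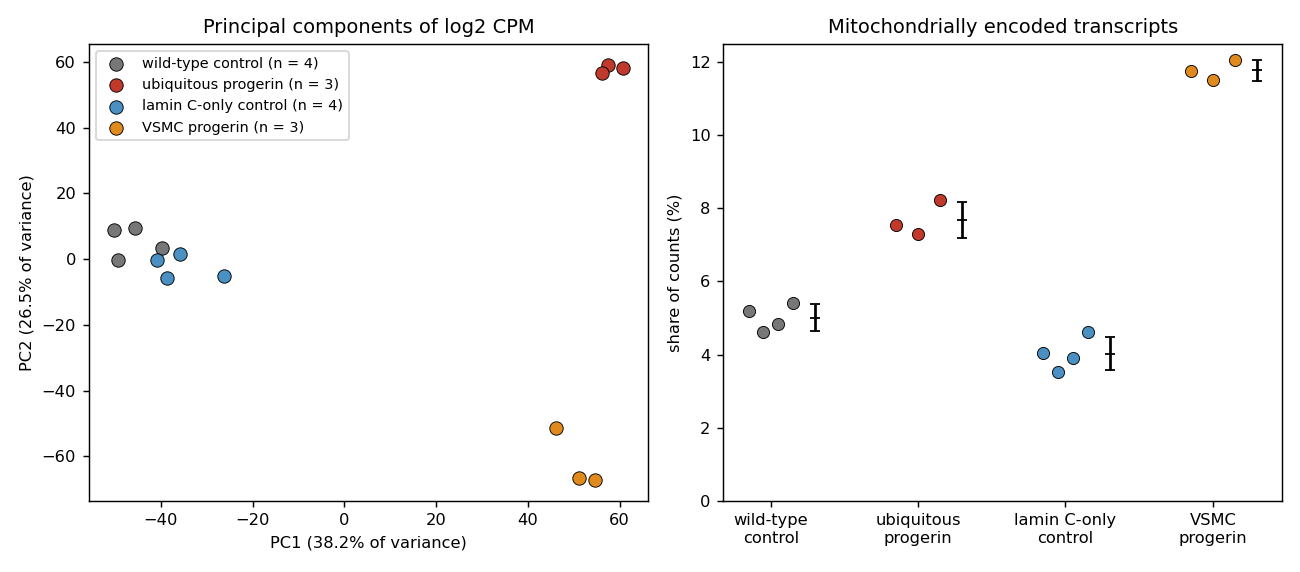
Principal components 1 and 2 of log2 CPM for the 14 libraries (left), and the share of counts from mitochondrially encoded genes in percent (right), with 1 point per library, coloured by group, and bars for the group mean and SD. The ubiquitous progerin and VSMC progerin libraries lie apart from their controls and from each other, and the mitochondrial share is 11.8% in VSMC progerin against 4.02% in lamin C-only control.

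Ubiquitous progerin was compared with wild-type control to ask what progerin in every cell does to the intimal transcriptome. Macrophage genes rose the most: Itgam, a leukocyte integrin (ENSMUSG00000030786, chromosome 7, 128062640 to 128118491), went from 1.68 ± 0.56 CPM (SD, n = 4) to 50.1 ± 5.3 CPM (n = 3), a log2 change of 4.90 ± 0.21 (SE). Endothelial genes fell, among them Tek, the receptor of the angiopoietins (ENSMUSG00000006386, chromosome 4, 94739289 to 94874976), from 1243 ± 52 to 503 ± 16 CPM, a log2 change of -1.30 ± 0.06. Collagen, interferon and YAP-related genes were mostly lower, and ribosomal protein and mitochondrially encoded genes were higher. As lists these did not hold with an estimated correlation (camera adjusted p = 0.37, 0.67, 0.37, 0.53 and 0.53), nor did the macrophage (0.12) and endothelial (0.35) lists. Lmna itself did not pass the test (log2 change -0.02 ± 0.07, adjusted p = 0.80), nor did Apoe (-0.18 ± 0.09, adjusted p = 0.087), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. By that test 7784 genes were called, 54.6% of those tested, 3746 higher and 4038 lower, and 1306 of the higher and 839 of the lower genes had an absolute log2 fold change of at least 1.

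Among the genes with the largest changes in ubiquitous progerin, Mrc1, a macrophage mannose receptor (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), rose by 4.85 ± 0.25 on the log2 scale, and Cd33, a lectin of myeloid cells (ENSMUSG00000004609, chromosome 7, 43524216 to 43544428), rose by 4.61 ± 0.45. Bcan, which encodes the proteoglycan brevican (ENSMUSG00000004892, chromosome 3, 87987531 to 88000230), fell by 5.30 on the log2 scale, from a mean of 28.4 CPM to 0.714 CPM. Ackr4, a scavenging chemokine receptor (ENSMUSG00000079355, chromosome 9, 104084157 to 104126933), fell by 3.43, and the secreted protease gene Klk10 (ENSMUSG00000030693, chromosome 7, 43781035 to 43785410) had a log2 change of -3.08 ± 0.21. The adjusted p of these genes ran from 6.0e-12 for Itgam to 7.4e-06 for Ackr4 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

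Of the 24 endothelial identity genes, 16 fell and 5 rose in ubiquitous progerin, the same numbers when adjusted over the list alone, with a median log2 change of -0.49 (camera adjusted p = 7.9e-05, and adjusted p = 0.35 with an estimated correlation). Icam2, an endothelial adhesion molecule, fell by 1.81 on the log2 scale (325 ± 46 to 92.8 ± 6.4 CPM), and Clec14a, a lectin of the vascular endothelium, fell by 1.08. The share of counts from Pecam1, an adhesion molecule of endothelial cells, was 1.16% ± 0.04 in wild-type control and 1.19% ± 0.03 in ubiquitous progerin. The 24 mesenchymal transition genes went both ways, with 7 higher and 8 lower, also when adjusted over the list alone, and a median of 0.08 (camera adjusted p = 0.89). In that list Mmp14, a membrane-bound matrix metalloproteinase, rose by 1.36 ± 0.09 on the log2 scale, while Twist1, a transcription factor of mesenchymal transition, fell from 139 ± 16 to 45.7 ± 1.6 CPM. Sparc, a matrix glycoprotein, fell by 0.65 and Vim, the intermediate filament vimentin, by 0.59, the latter from 3059 ± 161 to 2037 ± 35 CPM.

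Of the 20 collagen and collagen-processing genes, 11 fell and 1 rose (12 and 1 when adjusted over the list alone), with a median of -0.39 (camera adjusted p = 0.012, and adjusted p = 0.37 with an estimated correlation). Lox, the enzyme that cross-links collagen and elastin, fell by 0.88 on the log2 scale, as did Col4a1, a chain of basement membrane collagen. In the non-collagen matrix list 9 of 23 genes fell and 3 rose, also when adjusted over the list alone, at a median of -0.27 (camera adjusted p = 0.059). That list was called lower with no filter (adjusted p = 0.024), with only the groups compared (0.043) and without wild-type control pool 4 (0.038) or ubiquitous progerin pool 3 (0.041). Fbln2, a fibulin of elastic and basement membrane matrix, fell by 1.44, from 2096 ± 129 to 770 ± 76 CPM. TGF-beta signalling genes were divided, with 11 of 28 higher and 10 lower (12 and 10 when adjusted over the list alone; camera adjusted p = 0.88). Pmepa1, a transcriptional target and feedback inhibitor of the pathway, fell by 1.28 and Smad3, one of its signal transducers, by 1.06, while the co-receptor Tgfbr3 rose by 1.17 ± 0.08. Smooth muscle contractile genes were lower in 9 and higher in 3 of 20, also when adjusted over the list alone (median -0.68, camera adjusted p = 0.14), and the actin-binding genes Cald1 and Tpm1 fell by 1.09 and 0.89. Tagln, of the same list and chosen after its values were seen, rose from 258 ± 70 to 774 ± 36 CPM (log2 change 1.59, adjusted p = 5.9e-05 by edgeR). Of 15 adventitial fibroblast markers 2 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.33), and Pi16 fell by 1.81.

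Of the 23 macrophage and foam cell genes, 20 rose and 0 fell in ubiquitous progerin by edgeR (22 and 0 when adjusted over the list alone), with a median log2 change of 3.14 (camera adjusted p = 8.2e-18, and adjusted p = 0.12 with an estimated correlation). Lymphocyte markers did not pass as a list (3 of 11 higher and 1 lower, 3 and 0 when adjusted over the list alone; camera adjusted p = 0.43). The leukocyte adhesion and chemokine genes went both ways, with 6 of 22 higher and 7 lower (camera adjusted p = 0.46), the same numbers when adjusted over the list alone. Csf1, a growth factor of macrophages, fell by 1.58 on the log2 scale, and Vcam1, an adhesion molecule for leukocytes, fell by 0.83. Interferon response genes fell in 14 and rose in 4 of 20, also when adjusted over the list alone (median -0.60, camera adjusted p = 0.0081, and adjusted p = 0.67 with an estimated correlation). Lpl, lipoprotein lipase, rose by 1.96 ± 0.14 in a cholesterol and lipoprotein list with 9 of 20 genes higher and 5 lower (10 and 5 when adjusted over the list alone; camera adjusted p = 0.12).

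The p53 target and senescence list was called higher with 6 of 18 genes up and 5 down, also when adjusted over the list alone (median 0.11, camera adjusted p = 0.037, and adjusted p = 0.37 with an estimated correlation). Its call ended with limma-voom (adjusted p = 0.30), with the deposited log2 values (adjusted p = 0.30) and without wild-type control pool 1 (adjusted p = 0.071). Within it Sesn1, a stress-induced inhibitor of mTORC1, rose from 67.4 ± 3.8 to 264 ± 32.5 CPM (log2 change 1.97 ± 0.08), and Trp53inp1, a p53-induced nuclear protein, rose by the same 1.97. YAP and mechanosensitive genes fell in 13 and rose in 3 of 21, also when adjusted over the list alone (median -0.51, camera adjusted p = 0.037, and adjusted p = 0.37 with an estimated correlation). That call ended without wild-type control pool 1 (adjusted p = 0.054) or ubiquitous progerin pool 1 (adjusted p = 0.065). Srf, the serum response factor, fell by 1.10, and Axl, a receptor tyrosine kinase, rose by 1.64 ± 0.12.

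Cytosolic ribosomal protein genes rose in 23 of 23 cases in ubiquitous progerin, also when adjusted over the list alone (median 0.43, camera adjusted p = 1.3e-06, and adjusted p = 0.53 with an estimated correlation), with Rps3 at 0.84 ± 0.08, a value that is uncertain because its pseudogenes share reads. Mitochondrially encoded genes rose in 12 of 13 (13 when adjusted over the list alone; median 0.53, camera adjusted p = 7.4e-05, and adjusted p = 0.53 with an estimated correlation), with mt-Nd6, a subunit of respiratory complex I, at 0.92 ± 0.07. Nuclear genes of oxidative phosphorylation rose in 11 of 21, also when adjusted over the list alone (median 0.20, camera adjusted p = 0.042, and adjusted p = 0.75 with an estimated correlation), a call that ended without wild-type control pool 1 (adjusted p = 0.071) or ubiquitous progerin pool 2 (adjusted p = 0.092). In the circadian clock list, 6 of 16 genes rose and 3 fell (6 and 4 when adjusted over the list alone; camera adjusted p = 0.35), and the clock repressor Per1 rose by 1.50 ± 0.11. Of the 29 lists, 9 were called, 5 higher and 4 lower. None held with an estimated correlation in camera, where 2 lists had an unadjusted p under 0.05, and fry, which asks only for movement in 1 direction, called 21.

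**Figure D2:**
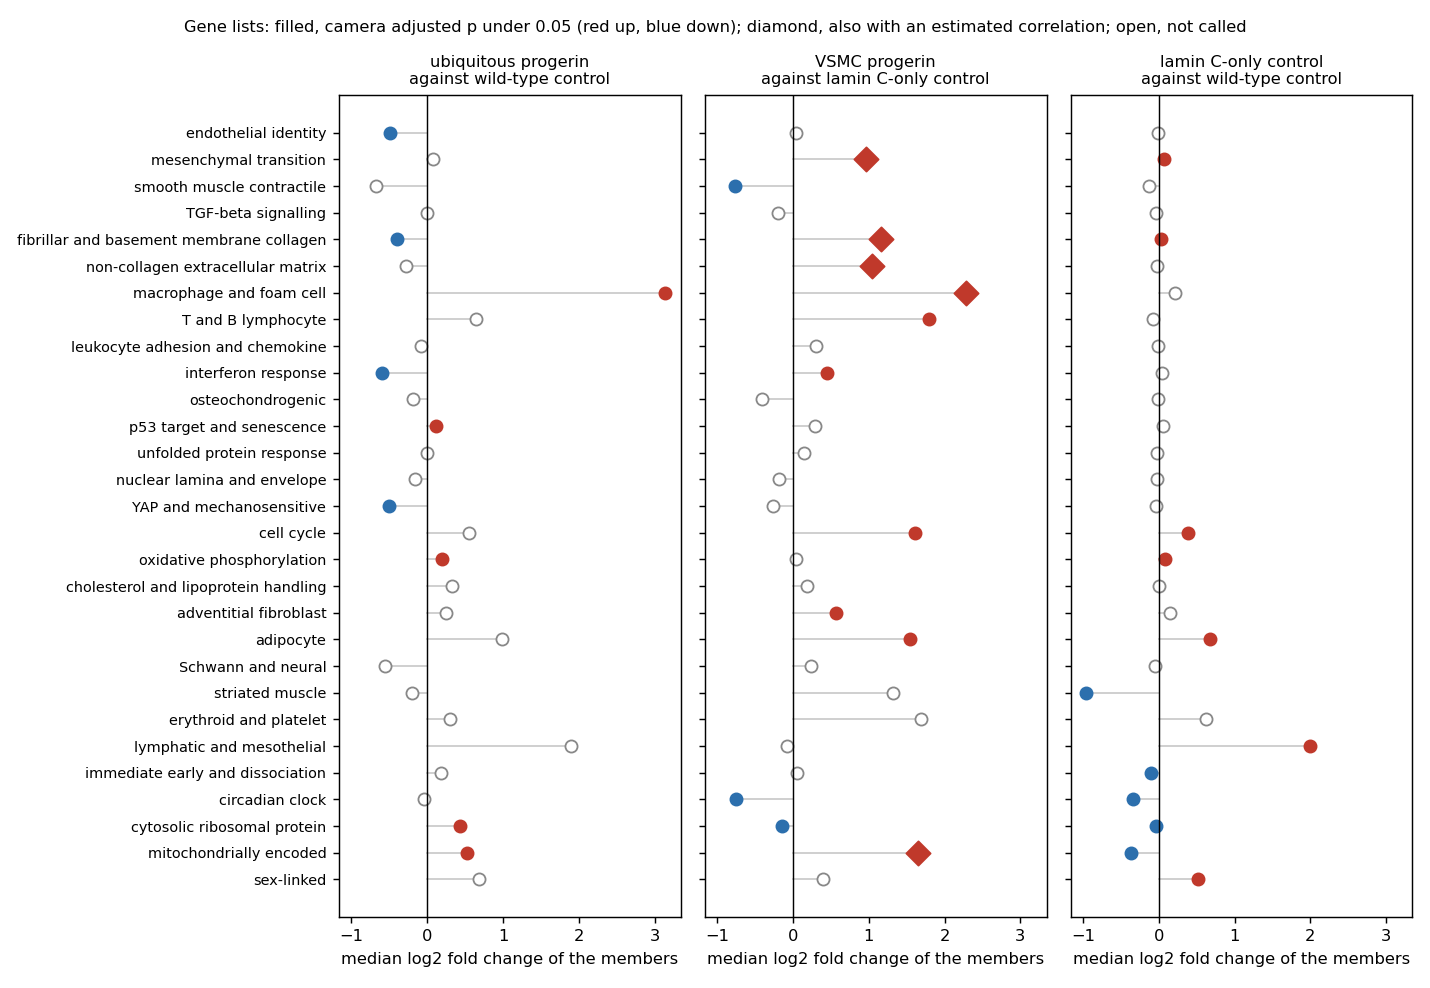
Median log2 fold change of the members of each of the 29 gene lists (horizontal axis) in the 3 comparisons between groups, with 1 symbol per list, filled where camera called the list (red higher, blue lower), a diamond where the call held with an estimated correlation, and open where not called. Collagen genes have a median of -0.39 in ubiquitous progerin and 1.16 in VSMC progerin, while macrophage genes lie at 3.14 and 2.28.

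VSMC progerin was compared with lamin C-only control to ask what the intima does with progerin that the labels give as specific to smooth muscle cells. Which cells of the lysate made progerin was not tested. Matrix and mesenchymal genes rose together: Col1a1, a chain of type I collagen (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), went from 17.5 ± 6.9 CPM (SD, n = 4) to 414 ± 55 CPM (n = 3), a log2 change of 4.57 ± 0.41. Sparc (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183) went from 1104 ± 39 to 3656 ± 142 CPM, a log2 change of 1.73 ± 0.05. Macrophage genes rose too, with Itgam at 3.67 ± 0.20 on the log2 scale. Endothelial identity genes went both ways. Lmna rose from 132 ± 7 to 227 ± 26 CPM (log2 change 0.78 ± 0.07, adjusted p = 1.4e-08), and Apoe fell by 0.32 on the log2 scale (adjusted p = 0.0057), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The Apoe call ended without VSMC progerin pool 2, at a log2 change of -0.23. The test called 5988 genes, 42.0% of those tested, 2705 higher and 3283 lower, and 1287 of the higher and 402 of the lower had an absolute log2 fold change of at least 1.

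The largest rises in VSMC progerin were in Cmah, an enzyme of sialic acid metabolism (ENSMUSG00000016756, chromosome 13, 24327404 to 24477377), from 1.02 ± 0.38 to 163 ± 52 CPM (log2 change 7.31 ± 0.43), and in Lrg1, a secreted glycoprotein that modulates TGF-beta signals in vessels (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001), from 4.24 ± 1.09 to 291 ± 57 CPM (6.10 ± 0.23). Postn, the matrix protein periostin (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), rose by 4.91 ± 0.57. Atp1b1, a subunit of the sodium pump (ENSMUSG00000026576, chromosome 1, 164437109 to 164458355), fell by 4.19 on the log2 scale, from 67.2 ± 3.2 to 3.62 ± 2.27 CPM. Gdf6, a ligand of the BMP family (ENSMUSG00000051279, chromosome 4, 9844372 to 9862345), fell by 3.84, and Slc26a4, an anion exchanger (ENSMUSG00000020651, chromosome 12, 31519827 to 31559969), fell by 3.74. Their adjusted p lay between 2.0e-09 for Lrg1 and 4.7e-05 for Postn by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

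Of the 24 mesenchymal transition genes, 19 rose and 3 fell in VSMC progerin, also when adjusted over the list alone, at a median log2 change of 0.96 (camera adjusted p = 1.7e-10, and adjusted p = 0.0032 with an estimated correlation). The matrix metalloproteinases Mmp2 and Mmp14 rose, Mmp2 from 215 ± 11 to 652 ± 17 CPM and Mmp14 by 1.63 ± 0.09 on the log2 scale, while Twist1 fell by 1.65, from 128 ± 9 to 40.9 ± 0.8 CPM. Collagen genes rose in 18 and fell in 1 of 20, also when adjusted over the list alone (median 1.16, camera adjusted p = 5.2e-17, and adjusted p = 0.0032 with an estimated correlation). Col5a2, a fibrillar collagen chain, went from 507 ± 23 to 1521 ± 44 CPM (1.59 ± 0.06), and Serpinh1, a collagen chaperone, rose by 0.83 ± 0.06. Non-collagen matrix genes rose in 14 and fell in 3 of 23, also when adjusted over the list alone (median 1.04, camera adjusted p = 8.9e-09, and adjusted p = 0.0039 with an estimated correlation), and Fbln5, an organiser of elastic fibres, rose from 431 ± 26 to 2101 ± 87 CPM (2.29 ± 0.10). Chad, a cartilage matrix protein of the osteochondrogenic list, rose by 3.74 ± 0.18, in a list with 4 of 14 genes higher and 4 lower (5 and 4 when adjusted over the list alone; camera adjusted p = 0.28).

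Endothelial identity genes rose in 10 and fell in 9 of 24 in VSMC progerin, also when adjusted over the list alone (median 0.04, camera adjusted p = 0.86). The receptors Flt1, of vascular endothelial growth factor, and Tie1 rose by 1.73 ± 0.17 and 0.82 ± 0.06, while Clec14a and the endothelial phosphatase Ptprb fell by 1.16 and 0.91. Pecam1 took 1.16% ± 0.04 of the counts in lamin C-only control and 0.857% ± 0.018 in VSMC progerin. Smooth muscle contractile genes fell in 9 and rose in 1 of 20 (9 and 2 when adjusted over the list alone; median -0.76, camera adjusted p = 0.022, and adjusted p = 0.44 with an estimated correlation). Mylk, myosin light chain kinase, fell by 0.95, whereas Cald1 rose by 1.12 ± 0.07. Among TGF-beta signalling genes 9 of 28 rose and 15 fell, also when adjusted over the list alone (median -0.19, camera adjusted p = 0.60). Pmepa1 and the ligand Tgfb1 rose by 1.17 ± 0.07 and 0.71 ± 0.09, and Id2, an inhibitor of DNA-binding factors induced by BMP signals, fell by 1.06.

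Macrophage and foam cell genes rose in 21 and fell in 1 of 23 in VSMC progerin, also when adjusted over the list alone (median 2.28, camera adjusted p = 6.1e-18, and adjusted p = 0.018 with an estimated correlation). Csf1r, the receptor of the macrophage growth factor, went from 7.19 ± 1.51 to 66.1 ± 5.0 CPM (3.21 ± 0.18). Lymphocyte markers rose in 6 of 11 (8 when adjusted over the list alone; median 1.80, camera adjusted p = 0.012, and adjusted p = 0.071 with an estimated correlation). Interferon response genes rose in 15 of 20, also when adjusted over the list alone (median 0.45, camera adjusted p = 0.00024, and adjusted p = 0.41 with an estimated correlation), with Oas2, an antiviral RNA sensor, at 3.05 ± 0.40. Ccl8, a chemokine for monocytes, rose by 5.36 ± 0.40 in a leukocyte adhesion list with 10 of 22 genes higher and 3 lower (10 and 5 when adjusted over the list alone; camera adjusted p = 0.13). Cell cycle genes rose in 12 of 22, also when adjusted over the list alone (median 1.61, camera adjusted p = 0.00032, and adjusted p = 0.16 with an estimated correlation), among them Top2a, a topoisomerase of dividing cells, at 1.93 ± 0.25.

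Markers of some other cell types rose with the matrix genes in VSMC progerin. Adventitial fibroblast markers rose in 9 and fell in 1 of 15, also when adjusted over the list alone (median 0.57, camera adjusted p = 0.00013, and adjusted p = 0.25 with an estimated correlation), with Pi16 going from 230 ± 8 to 698 ± 86 CPM. Adipocyte markers rose in 9 of 14, also when adjusted over the list alone (median 1.55, camera adjusted p = 0.0060, and adjusted p = 0.44 with an estimated correlation). Erythroid and platelet genes were higher in 8 of 11, also when adjusted over the list alone, and striated muscle genes in 5 of 10 (6 when adjusted over the list alone), with medians of 1.69 and 1.32 (camera adjusted p = 0.069 and 0.065). Both lists passed without VSMC progerin pool 2 (adjusted p = 0.0061) and with the deposited log2 values (0.010 and 0.0099). The erythroid and platelet list also passed with no low-count filter, with limma-voom (0.011) and without lamin C-only control pool 2 (0.047) or VSMC progerin pool 1 (0.023), and the striated muscle list with a filter of 1 CPM in 3 libraries (0.030). With single libraries left out their adjusted p reached 0.28 and 0.14, and the mean centred log2 CPM of the erythroid list was 2.83 in pool 3 against 0.55 and 0.10 in pools 1 and 2. Mitochondrially encoded genes rose in 13 of 13, also when adjusted over the list alone (median 1.65, camera adjusted p = 1.1e-52, and adjusted p = 0.0039 with an estimated correlation), with mt-Nd4 at 1.61 ± 0.07. Circadian clock genes fell in 11 and rose in 2 of 16 (12 and 2 when adjusted over the list alone; median -0.76, camera adjusted p = 0.00022, and adjusted p = 0.16 with an estimated correlation), and the clock repressor Nr1d1 fell by 1.31. A different time of day at which the groups were killed could also change clock genes. The labels do not give that time, and it was not tested. The p53 target list had 9 of 18 genes higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.29). Sesn1 fell by 0.95 and Plk2, a stress-induced kinase, by 1.27. YAP and mechanosensitive genes were higher in 5 and lower in 11 of 21, also when adjusted over the list alone (camera adjusted p = 0.18). Lpl rose by 1.94 ± 0.14. Ribosomal protein genes fell in 11 of 23 (15 when adjusted over the list alone; median -0.15, camera adjusted p = 0.045, and adjusted p = 0.64 with an estimated correlation). That call ended under RLE size factors (adjusted p = 0.070), with a filter of 1 CPM in 3 libraries (0.076), with only the groups compared (0.13), and without lamin C-only control pool 2 (0.099), lamin C-only control pool 4 (0.084) or VSMC progerin pool 1 (0.22). It also ended with the pool number as a block, and without the mitochondrially encoded genes (adjusted p = 0.071), the latter a setting chosen after the data were seen. Of the 29 lists, 13 were called, 10 higher and 3 lower. The 5 that held with an estimated correlation were mesenchymal transition, collagen, non-collagen matrix, macrophage and mitochondrially encoded genes.

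**Figure D3:**
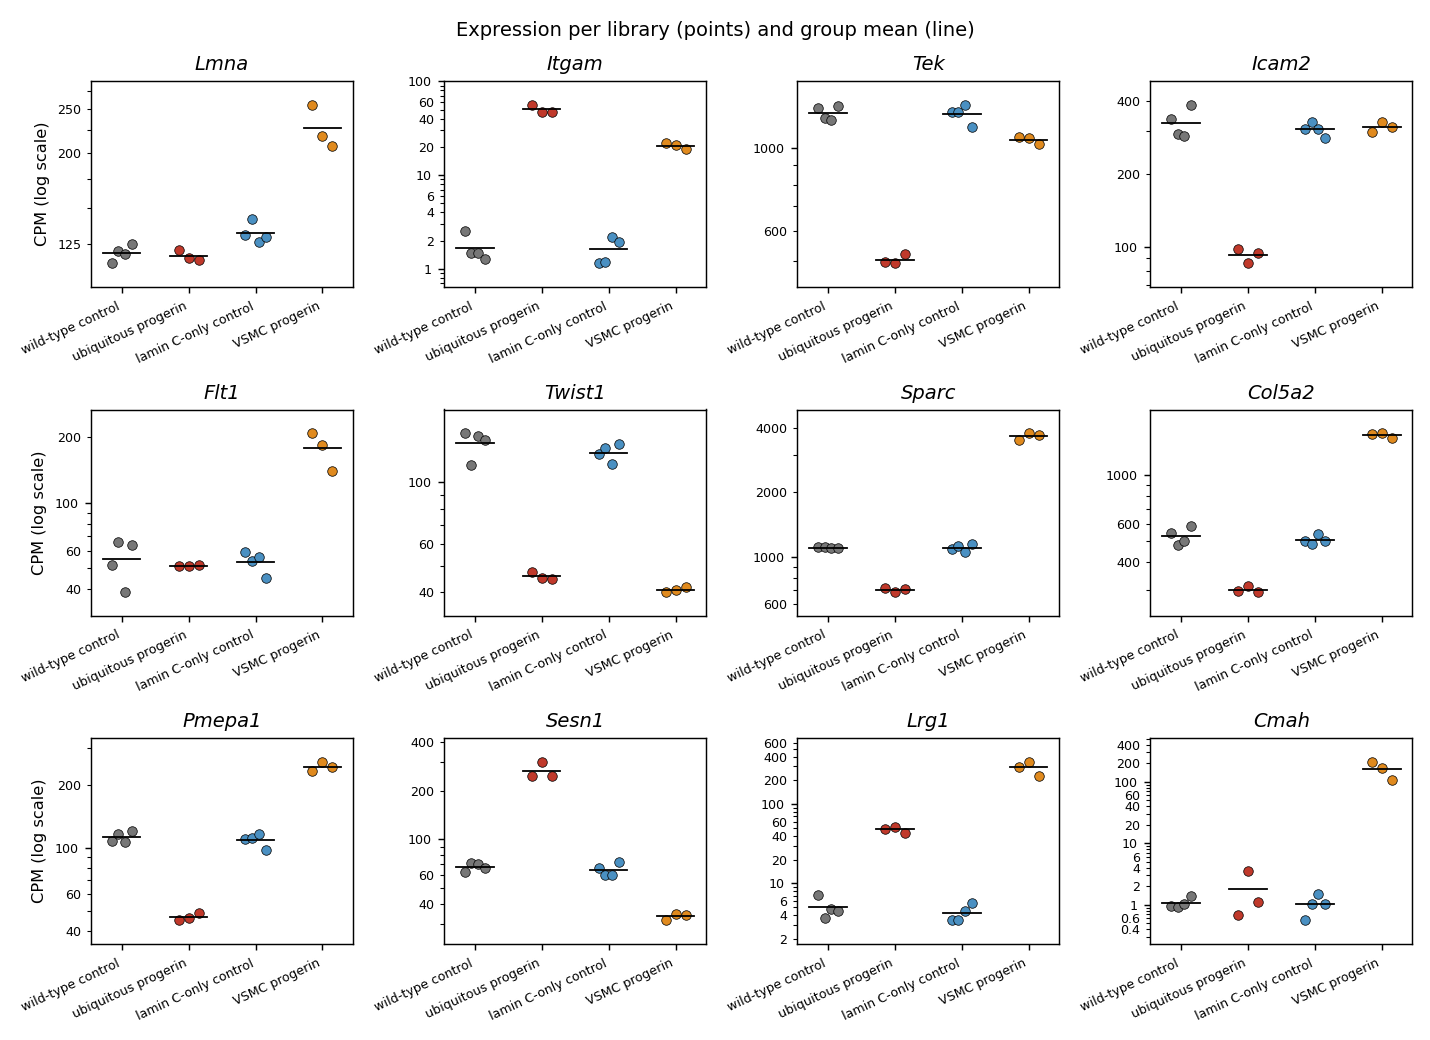
TMM-scaled CPM on a logarithmic axis for 12 named genes in each of the 14 libraries, with 1 point per library, grouped by genotype, and a line at the group mean. Sparc lies at 702 CPM in ubiquitous progerin and 3656 CPM in VSMC progerin, against 1104 CPM in both control groups.

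The controls were compared to ask what differs with the lamin C-only allele without progerin. The labels give no age, sex or time of day at which the mice were killed. In ubiquitous progerin 1 of 4 sex-linked genes was called higher, 0 when adjusted over the list alone (median 0.68, camera adjusted p = 0.45). Ddx3y, of that list, lay at 26.7 to 43.1 CPM in wild-type control and 48.9 to 97.4 CPM in ubiquitous progerin. In VSMC progerin 0 of the 4 were called (median 0.40, camera adjusted p = 0.52). A different sex mix of the pools was not tested. Few single genes differed between lamin C-only control and wild-type control. Arntl, which encodes the clock activator BMAL1 (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126), rose from 10.7 ± 0.7 CPM (SD, n = 4) to 21.7 ± 2.4 CPM (n = 4), a log2 change of 1.01 ± 0.13. Its relative Npas2 (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236) rose by 0.81 ± 0.16. The clock repressor Bhlhe41 (ENSMUSG00000030256, chromosome 6, 145858243 to 145865558) fell by 0.87 on the log2 scale. Lmna (log2 change 0.14 ± 0.06, adjusted p = 0.62) and Apoe (0.12 ± 0.08, adjusted p = 0.82) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. It called 25 genes, 13 higher and 12 lower, while 1052 had an unadjusted p under 0.05. The count ran from 8 to 45 with single libraries left out, and was 40 with no filter, 16 with only the groups compared and 103 with DESeq2.

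The largest rise between the controls was in Akap12, a scaffold of protein kinase A (ENSMUSG00000038587, chromosome 10, 4266380 to 4359470), from 6.50 ± 0.525 to 26.9 ± 8.4 CPM (2.05 ± 0.28, adjusted p = 0.013 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Vcan, the proteoglycan versican, rose by 0.89 ± 0.16, Cenpf, a kinetochore protein, by 1.51 ± 0.25, and Col18a1, a basement membrane collagen, by 0.73 ± 0.10. Crispld2, a secreted glycoprotein, fell by 1.17, the transcription factor Pou6f1 by 0.71, mt-Nd2 by 0.41 and the calcium-binding gene S100a11 by 0.40. The adjusted p of these genes lay between 0.0034 for Arntl and 0.036 for Npas2, and the calls of Akap12, Vcan, Npas2, Bhlhe41, mt-Nd2, S100a11 and Cenpf ended when 1 or more single libraries were left out. With only the groups compared, the calls of Crispld2, Col18a1, Cenpf, Vcan and mt-Nd2 ended.

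Camera called 12 of the 29 lists between the controls, 7 higher and 5 lower. None held with an estimated correlation, where 5 lists had an unadjusted p under 0.05, and fry called 1. Mitochondrially encoded genes fell in 4 of 13 (13 when adjusted over the list alone; median -0.36, camera adjusted p = 5.0e-33, and adjusted p = 0.081 with an estimated correlation). In the clock list 2 of 16 genes rose and 1 fell (2 and 11 when adjusted over the list alone; median -0.34, camera adjusted p = 1.3e-07, and adjusted p = 0.11 with an estimated correlation). A different time of day of killing was not tested for these clock genes. The cell cycle list had 1 gene higher of 22 (2 when adjusted over the list alone; median 0.38, camera adjusted p = 1.9e-06, and adjusted p = 0.11 with an estimated correlation). Collagen genes were higher in 1 of 20 (5 when adjusted over the list alone; median 0.03, camera adjusted p = 0.00043, and adjusted p = 0.18 with an estimated correlation). Of the mesenchymal transition genes 0 of 24 were called by edgeR over all genes and 5 rose when adjusted over the list alone (median 0.07, camera adjusted p = 0.011, and adjusted p = 0.25 with an estimated correlation). The collagen and mesenchymal calls ended without lamin C-only control pool 4 (both adjusted p = 0.062), and the mesenchymal call also without pool 3 (0.055). The other lists called higher were oxidative phosphorylation, adipocyte, lymphatic and mesothelial, and sex-linked genes, and those called lower were striated muscle, immediate early and ribosomal protein genes. Their camera adjusted p lay between 0.00052 and 0.045, and their adjusted p with an estimated correlation between 0.32 and 0.72. Of these, the striated muscle call held with each single library left out. The other calls ended in at least 1 such case, with a highest adjusted p of 0.50 for oxidative phosphorylation, 0.66 for adipocyte, 0.34 for lymphatic and mesothelial, 0.16 for sex-linked, 0.42 for immediate early and 0.32 for ribosomal protein genes. Endothelial identity genes showed a median of -0.01 (camera adjusted p = 0.68). Lamin C-only control pool 4 had higher adventitial fibroblast markers than the other pools of its group, and without it 7 lists were called.

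Both progerin effects were compared directly, as the ubiquitous progerin effect minus the VSMC progerin effect. The models also differ in lamin background and in Cre, and no group carried Cre without progerin. These differences cannot be told apart here from where progerin is made. Collagen genes differed in 1 direction: 18 of 20 were lower and 0 higher by edgeR, also when adjusted over the list alone, with a median difference of -1.45 on the log2 scale (camera adjusted p = 6.9e-17, and adjusted p = 0.0050 with an estimated correlation). Col1a1 differed by -4.21 ± 0.57, with 18.7 ± 7.8 CPM (SD, n = 4) in wild-type control and 23.8 ± 10.7 CPM (n = 3) in ubiquitous progerin. Hhipl1, a secreted protein of the hedgehog-interacting family (ENSMUSG00000021260, chromosome 12, 108306270 to 108330869), rose by 3.07 with ubiquitous progerin and fell by 1.89 with VSMC progerin. The test called 6310 genes for the difference, 3203 with a positive and 3107 with a negative value, of which 882 and 1119 had an absolute value of at least 1.

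In the other direction, Galnt18, a glycosyltransferase that starts O-linked chains (ENSMUSG00000038296, chromosome 7, 111471661 to 111779977), fell by 2.31 with ubiquitous progerin and rose by 2.08 with VSMC progerin. St14, a membrane serine protease (ENSMUSG00000031995, chromosome 9, 31089402 to 31131853), rose by 4.16 with VSMC progerin and had a log2 change of -0.33 with ubiquitous progerin, which did not pass. The difference was -4.40 ± 0.39 for Galnt18 and -4.49 ± 0.36 for St14. Lmna differed by -0.80 ± 0.10 (adjusted p = 1.1e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 62 named genes tested for the difference, 53 passed, and 19 were called in opposite directions, among them Sparc, Cald1, Pmepa1, Sesn1 and Pi16. The named genes were picked for large changes or small p in these same data, some by this difference, so many were bound to pass. Of all genes tested, 44.2% were called for the difference.

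Of the 29 lists, 9 differed between both effects by camera, 2 with positive and 7 with negative values, and 3 held with an estimated correlation. These 3 were collagen, non-collagen matrix (16 of 23 lower, 1 higher, also when adjusted over the list alone; median -1.27, camera adjusted p = 2.1e-09, and adjusted p = 0.0060 with an estimated correlation) and mesenchymal transition (12 of 24 lower, 1 higher; 13 and 1 when adjusted over the list alone; median -0.55, camera adjusted p = 2.3e-05, and adjusted p = 0.032 with an estimated correlation). Endothelial identity genes were lower in 16 and higher in 6 of 24, also when adjusted over the list alone (median -0.56, camera adjusted p = 0.00018, and adjusted p = 0.23 with an estimated correlation). Interferon response genes were lower in 15 of 20 (17 when adjusted over the list alone; median -1.14, camera adjusted p = 1.0e-07, and adjusted p = 0.23 with an estimated correlation). Adventitial fibroblast, clock, ribosomal protein and mitochondrially encoded genes had median differences of -0.84, 0.91, 0.61 and -1.15 (camera adjusted p = 0.00016, 0.00018, 3.1e-09 and 1.1e-11), with adjusted p = 0.28, 0.23, 0.35 and 0.23 with an estimated correlation. For the clock genes, times of killing that differ between groups were not tested. The macrophage list did not pass (7 of 23 higher, 1 lower, also when adjusted over the list alone; camera adjusted p = 0.14), but was called higher without lamin C-only control pool 1 (adjusted p = 0.030). Across all 4 comparisons the median, the mean and the camera direction of a list differed in sign in 17 of 116 cases, 0 of them called by camera. In ubiquitous progerin these were TGF-beta signalling, leukocyte adhesion, unfolded protein response, adventitial fibroblast, striated muscle and clock genes.

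The genes called in both progerin comparisons overlapped. Of them 1126 rose in both, where independent lists of the same sizes would share 710, and 1231 fell in both against 929. Genes that rose with ubiquitous progerin and fell with VSMC progerin numbered 910 against 862, and those that did the opposite were fewer than the 765 of independent lists, at an odds ratio of 0.689. By Fisher's exact test over the 14269 genes the adjusted p values were 7.2e-84, 9.0e-39, 0.030 and 6.9e-14. In all, 2357 genes moved the same way and 1519 moved opposite ways. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = 0.36 and Spearman rho = 0.20. Lpl, Mmp14 and Itgam rose in both comparisons and Clec14a and Twist1 fell in both.

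**Figure D4:**
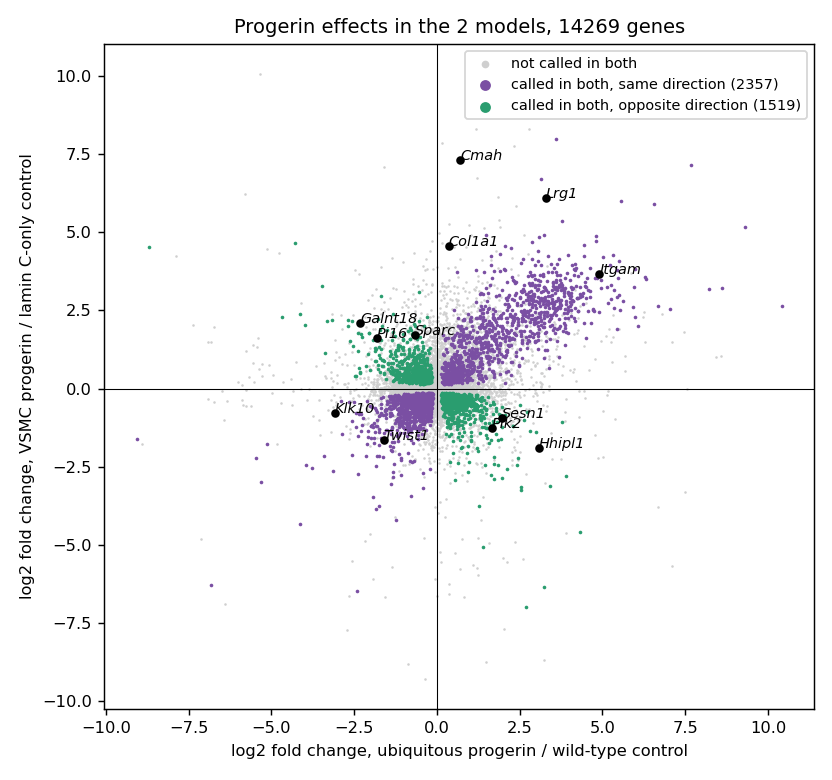
Log2 fold change of each tested gene in VSMC progerin against lamin C-only control (vertical axis) and in ubiquitous progerin against wild-type control (horizontal axis), with 1 point per gene, coloured by whether it was called in both comparisons in the same direction or in opposite directions. Genes called the same way number 2357 and those called opposite ways 1519.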

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

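The tests of less material in the lysate, of dilution of endothelial RNA and of genes near Lmna between the controls were chosen after the results were seen, and the other tests of this part before. Genes named in this part that are outside the rule for named genes were chosen after their values were seen.

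Both progerin effects differed for 53 of 62 named genes by edgeR's quasi-likelihood test of the difference, ubiquitous minus VSMC progerin on the log2 scale. Many were bound to pass, since they were picked for large changes or small p in these same data, some by this difference. Of all genes tested, 44.2% were called for it. Mesenchymal, contractile and TGF-beta genes had Sparc -2.38, Vim -0.39, Mmp2 -1.37, Cald1 -2.21, Tpm1 -0.57, Mylk 1.27, Pmepa1 -2.45, Smad3 -0.67, Tgfbr3 1.41, Tgfb1 -0.90 and Id2 1.91. Matrix genes had Lox -1.35, Col4a1 -1.36, Fbln2 -0.83, Col5a2 -2.40, Serpinh1 -1.50, Fbln5 -2.60, Chad -3.12, Postn -3.90 and Col1a1 -4.21, and the fibroblast marker Pi16 -3.41. Endothelial genes had Tek -1.07, Icam2 -1.85, Ptprb 0.49, Tie1 -1.13 and Flt1 -1.83. Immune genes had Itgam 1.24, Mrc1 1.15, Csf1 -0.86, Vcam1 -0.56 and Oas2 -1.52. Stress, growth and clock genes had Sesn1 2.92, Trp53inp1 2.05, Plk2 2.93, Srf -0.52, Top2a -1.07, Per1 2.15 and Nr1d1 1.19. The others were Lmna -0.80, Bcan -2.30, Ackr4 -1.26, Klk10 -2.29, Cmah -6.60, Lrg1 -2.82, Atp1b1 2.94, Gdf6 1.99, Slc26a4 1.99, mt-Nd6 -0.72, mt-Nd4 -1.34, Rps3 1.08, Hhipl1 4.96, Galnt18 -4.40 and St14 -4.49. Lists that differed by camera had medians of -0.56 (endothelial identity), -0.55 (mesenchymal transition), -1.45 (collagen), -1.27 (non-collagen matrix), -1.14 (interferon response), -0.84 (adventitial fibroblast), 0.91 (circadian clock), 0.61 (ribosomal protein) and -1.15 (mitochondrially encoded). With an estimated correlation the mesenchymal, collagen and non-collagen matrix lists held, and the others did not (adjusted p = 0.23 for endothelial, interferon, clock and mitochondrially encoded genes, 0.28 for fibroblast and 0.35 for ribosomal genes).

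In 14 of 212 groups of 4 libraries, 1 library lay far from the other 3, where chance does so in about 1 in 20 groups. In log2 CPM these were Ackr4 in lamin C-only control pool 4 (5.79 against 5.54 to 5.57) and Cenpf in pool 2 of that group (1.24 against 1.83 to 1.92). In wild-type control they were Rps3 in pool 1 (10.05 against 10.27 to 10.30), Postn (3.75 against 1.64 to 1.91), Atp1b1 (5.98 against 6.24 to 6.26) and Col18a1 (7.16 against 6.64 to 6.66) in pool 2, Id2 (6.36 against 5.91 to 5.93), Plk2 (6.76 against 6.47 to 6.50) and Akap12 (2.53 against 2.75 to 2.79) in pool 3, and Pi16 (7.91 against at most 7.64) and Serpinh1 (7.68 against 7.51 to 7.53) in pool 4. Wild-type control pool 1 had counts for 14328 genes against 15188 to 15233. The mean centred log2 CPM of the endothelial identity list was -0.038 in lamin C-only control pool 3 against 0.04 to 0.05, and that of the adventitial fibroblast list 0.52 in pool 4 against -0.46 to -0.34.

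Collagen and mesenchymal genes rose in VSMC progerin, and smooth muscle of the media or adventitial fibroblasts carried into the lysate could raise them too. Carried-over contractile muscle is argued against weakly, since the contractile list had a median of -0.76 (interval -0.92 to -0.33) and Acta2 went from 172 to 86.1 CPM. Against this, Cald1 went from 212 to 461 CPM and Tagln (215 to 174 CPM) did not pass. Intervals in this paragraph are 95% bootstrap intervals over the genes of a list and hold no spread between pools. The contractile list passed camera (adjusted p = 0.022) but not with an estimated correlation (adjusted p = 0.44). Of its 20 genes 20 were tested, 0 were held by another list and 16 were at 1 CPM or more in the controls. Fibroblasts stay open: their markers outside the matrix lists had a median of 0.77 (0.09 to 1.55) beside 1.16 (0.79 to 1.75) for collagen, and Ly6a went from 418 to 1491 CPM while Gsn went from 546 to 384 CPM. In ubiquitous progerin the same medians were -0.68 (-1.02 to -0.09) and 0.13 (-0.43 to 0.59), and they decide nothing there, because collagen fell and the bound written beforehand assumed a rise; less carried-over material is also left open by the upper bound of 0.59. Smooth muscle cells low in contractile transcripts, and a change in the intimal cells themselves, were not tested.

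Endothelial identity genes fell in ubiquitous progerin while macrophage genes rose (camera adjusted p = 0.35 and 0.12 with an estimated correlation), so RNA of other cells could dilute endothelial RNA. Dilution as the whole cause is argued against weakly by 5 members called higher by edgeR (Gpihbp1 1.82, Emcn 1.17, Robo4 0.85, Egfl7 0.24 and Erg 0.13). The argument is weak because this test was chosen when these calls were known. Erg also lay near the threshold (adjusted p = 0.0499 by edgeR), and Gpihbp1 had an SE of 0.55. The log2 changes of the members differed beyond their errors (Cochran's Q 1229 on 23 degrees of freedom, across genes that are not independent replicates). A smaller part played by dilution stays open, as does a change in the kinds of endothelial cell present, which was not tested.

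Genes near Lmna were frequent among the 25 calls between the controls: 5 lay within 20 Mb of it (among them Arhgef2 0.32, Arhgef11 -0.30, Rps3a1 -0.31 and S100a11 -0.40), an odds ratio of 10.5 (Fisher's exact test, one-sided, adjusted p = 0.0015). Sequence variants linked to the engineered allele could do this. In VSMC progerin against lamin C-only control, where both groups carry the same allele, the odds ratio was 0.970. In ubiquitous progerin the odds ratio was 1.05. With 42.0% and 54.6% of all genes called there, a few linked genes could hardly move these ratios, so they decide nothing. Among ubiquitous progerin calls with an absolute log2 fold change of at least 1, the ratio was 0.914 (0.655 to 1.25). That was the test written beforehand, and it leaves the matter undecided there. With that minimum the controls gave 6.91 (1 of 7 calls, adjusted p = 0.46 by the same exact test). An effect of the lamin C-only allele on neighbouring genes was not tested.

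The real grouping called the most genes in ubiquitous progerin (7784, highest other split 4382), VSMC progerin (5988, highest other 2315) and lamin C-only control (25, highest other 0 by edgeR). Each count was matched by 1 of 35 splits of the same libraries, the real one, which is the lowest share that 35 splits can give. In both progerin comparisons, the only other splits with any call kept the 3 progerin libraries together, joined by 1 control library. They kept most of the real contrast, so 4382 and 2315 are not what a random regrouping gives. The remaining splits there called 0 genes by edgeR. Splits that mix groups that differ can also raise the spread and so call fewer genes. Chance is therefore made less likely but is not excluded. For the difference of effects, 12 of 100 drawn splits called as many as the real 6310, the highest other being 6784. All 12, the real one included, kept the 3 libraries of each progerin group together and exchanged control libraries at most, so they kept the contrast between the progerin groups and do not speak to chance. Splits that mixed the progerin libraries called at most 0 genes by edgeR, where mixing can raise the spread as well.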

How the results depend on the processing

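Leaving out the mitochondrially encoded genes and the genes near Lmna was chosen after the results were seen.

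Of 1528 values of named genes under alternatives, 1491 kept direction and call, 37 weakened and 0 reversed, and 74 of 83 results held throughout. Of 2287 values of lists, 2140 held, 80 weakened, 66 strengthened and 1 reversed, and 41 of 116 results held throughout. A minimum absolute log2 fold change of 1 left, by construction, 2145 genes in ubiquitous progerin, 1689 in VSMC progerin, 7 between the controls, 2001 for the difference and 750 the same way in both. Between the controls (25 genes), no filter gave 40, DESeq2 103 and only the groups compared 16; the cause was not tested. Leaving out single libraries gave 8 to 45 there: 45 without wild-type control pool 2, 13, 8 and 12 without pools 1, 3 and 4, and 16, 15 and 8 without lamin C-only control pools 1, 2 and 3. Lists called with an estimated correlation numbered 0, 5, 0 and 3 in ubiquitous progerin, VSMC progerin, the controls and the difference, and with fry, which does not compare a list with other genes, 21, 25, 1 and 17. With single libraries left out the controls had 7 to 14 lists called, with 7 without lamin C-only control pool 4. Without that pool the adventitial fibroblast list reversed from higher, not called, to lower, called, and its camera adjusted p ran from 0.0053 to 0.791 with single libraries left out; the cause was not tested. In ubiquitous progerin, Apoe passed with only the groups compared (-0.18, adjusted p = 0.035 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and the cause was not tested. In VSMC progerin it ran from -0.41 to -0.23 with single libraries left out, and its call ended without pool 2 (adjusted p = 0.052). Crispld2, Col18a1, Cenpf, Vcan and mt-Nd2 lost their calls between the controls with only the groups compared, while Arntl and Pou6f1 kept theirs throughout. Other counts ran from 6863 to 7965 (ubiquitous progerin), 5041 to 6216 (VSMC progerin), 5736 to 6562 (difference) and 2088 to 2901 (same way in both). The balance of higher and lower calls turned with RLE size factors (3986 and 3815 in ubiquitous progerin, 2910 and 2839 in VSMC progerin), with DESeq2 (4073 and 3892, 3010 and 2941), with only the groups compared in VSMC progerin (2829 and 2675) and without mitochondrially encoded genes (3922 and 3873, 2882 and 2871). Only the groups compared gave no value for the difference of effects, and its overlap was built from both separate fits. Without mitochondrially encoded genes VSMC progerin had 5753 calls, and without genes near Lmna the controls had 20.

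With the pool number as a block, 7536, 5806, 32 and 6253 genes, 9, 12, 12 and 9 lists and 2270 genes the same way in both were called, and the ribosomal protein list in VSMC progerin (camera adjusted p = 0.077) and Npas2 between the controls (adjusted p = 0.12 by edgeR) were not. Same-numbered pools had correlations of deviations of -0.05 to 0.06, -0.05 to 0.16 and -0.07 to 0.09, so the numbers do not pair the libraries.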

Other observations

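All genes named in this part were chosen after their values were seen, and the 3 added gene lists were written after the genes with the largest changes were seen but before the lists were tested. Adjusted p of these lists are over the 3 of them within a comparison.

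The nuclear lamina and envelope list passed camera in neither progerin comparison (adjusted p = 0.14 and 0.18, and 0.37 and 0.41 with an estimated correlation), and its members went both ways. In ubiquitous progerin, where 54.6% of all genes were called by edgeR, 10 of 19 fell and 4 rose (log2 changes), among them the nesprin genes Syne2 (-1.34) and Syne1 (-0.76), while Lbr, the lamin B receptor, rose (0.34). In VSMC progerin, with 42.0% of all genes called, 8 fell and 3 rose, with Lbr at -0.62, Syne1 at 0.60 and Sun2 at -0.64. The cholesterol exporters Abca1 (0.71) and Abcg1 (0.73) and the scavenger receptor Cd36 (2.58) rose in ubiquitous progerin, and Abcg1 (0.63) and Cd36 (1.49) rose in VSMC progerin too. The cholesterol list passed in neither (camera adjusted p = 0.12 and 0.24). In ubiquitous progerin that outcome held in 16 of 18 alternative settings, and fry was among those that called the list (adjusted p = 5.5e-06). In VSMC progerin the sterol synthesis genes Lss (-1.10) and Idi1 (-1.20) and the sterol regulator Insig1 (-1.16) fell, and Idi1 fell in ubiquitous progerin too (-0.66).

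A few single genes, not tested together as a group, also passed. Klf2, induced by laminar flow, fell in ubiquitous progerin (-0.94) and rose in VSMC progerin (0.63), as did the nitric oxide synthase Nos3 (-0.55 and 0.39). Snai1, a transcription factor of mesenchymal transition, rose in both (2.59 and 2.36), while its relative Snai2 fell in both (-0.91 and -0.51). Mgp, an inhibitor of calcification, fell in ubiquitous progerin (-0.61) and rose in VSMC progerin (1.04), and Bmp4 fell in both (-1.04 and -1.02).

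Hypothesis: ubiquitous progerin mice have higher glucocorticoid signalling. Of 21 glucocorticoid targets, 14 rose and 5 fell (median 1.31, camera unadjusted p = 3.5e-08, adjusted p = 1.1e-07, and adjusted p = 0.021 with an estimated correlation), as the hypothesis predicts, with Fkbp5 at 2.64 and Tsc22d3 at 1.73. In VSMC progerin 6 of the 21 rose and 8 fell (camera adjusted p = 0.60, and adjusted p = 0.78 with an estimated correlation). The data hold no hormone levels or times of sampling, so handling and time of day were not tested.

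Hypothesis: the VSMC progerin intima receives interleukin 6 type signals. Of 22 acute phase and interleukin 6 targets, 15 rose and 4 fell (median 1.22, camera unadjusted p = 8.6e-08, adjusted p = 2.6e-07, and adjusted p = 0.010 with an estimated correlation), as predicted. In ubiquitous progerin 15 of the 22 rose and 3 fell (median 0.95, camera adjusted p = 3.8e-06, and adjusted p = 0.020 with an estimated correlation), so the rise is not limited to VSMC progerin, with Socs3 at 1.50 and 1.66 and Lcn2 at 2.90 and 2.85. Leukocyte RNA as the source was not tested.

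Hypothesis: endothelial cells lose arterial identity with ubiquitous progerin. Of 20 arterial and Notch genes, 12 fell and 4 rose (median -0.41, camera p = 0.012 unadjusted and adjusted, and adjusted p = 0.021 with an estimated correlation), as predicted, with Jag1 at -1.32 and Hes1 at -0.65. In VSMC progerin 9 of the 20 rose and 5 fell (median 0.35), which did not pass (camera adjusted p = 0.075, and adjusted p = 0.087 with an estimated correlation), with Sema3g at 1.79 against -1.32 in ubiquitous progerin. A general fall of endothelial genes (16 of 24 identity genes fell) would lower these genes too, and was not told apart from a loss of arterial identity. Dilution by macrophage RNA would also lower them. As the whole cause it was argued against weakly above for the identity genes, and a smaller part played by it stays open.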
